A study of Caenorhabditis elegans with 3 samples.

How the data were processed

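Per the labels, the animals were wild-type Caenorhabditis elegans kept with bacteria that made PNGaseDJ, PNGaseF or DJ101A, a PNGase mutant without activity, and whole worms were used. RNA was taken with TRIzol and made into poly(A)-selected libraries for Illumina sequencing. The labels give 2 biological replicates for each of the 3 conditions, whereas the tables hold 1 count column per condition. Whether that column sums the replicates is not stated, and the columns carry no replicate number. Each column was therefore treated as 1 library, and the groups were taken from the labelled treatment.

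The counts are whole reads per gene, made by the authors with featureCounts 2.1.1, per the file headers. The header of the table with DJ101A and PNGaseDJ gives 4 threads, the paired flag without the option that counts read pairs, and strand setting 0, so reads of both strands were counted together. The series describes the run as single-end. Of the genes with 10 to 49 reads, 73.0% had an even count in the DJ101A column, 71.5% in the PNGaseDJ column and 66.5% in the PNGaseF column, as happens where both mates of a pair are counted. Counting intervals were therefore computed on read pairs, at 2 reads each. HISAT2, FastQC, MultiQC and DESeq2 are named in the submitters' processing notes without versions. The genome build and annotation, and the counting command for PNGaseF, are not given in the sources used here. Gene coordinates are those of the count table. Of its 46926 genes, 46917 were found by identifier in the Ensembl release 115 annotation of build WBcel235, 45513 (97.0%) had the same chromosome, start and end there, and 44111 took a symbol or sequence name from it. Coordinates are printed as the count table gives them.

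The log2 fold changes deposited by the authors are per-gene values from their comparison tables. They equalled log2 of the ratio of CPM plus 1 (counts scaled to a common library total), computed without a composition factor, for each gene of both tables within 1e-06. The PNGaseF counts deposited by the authors stand only in their comparison table, which lists 17582 genes whose counts sum to at least 11 over both libraries. The PNGaseF total of 62868888 reads was solved from the deposited log2 values of 101 abundant genes, which gave the same whole number each time. The genes listed held 62865633 of these reads. The 29344 genes not listed shared the remaining 3255 reads, and a gene not listed was given its highest possible PNGaseF count (10 minus its DJ101A count) in the comparison of both enzymes and left out of the comparison of PNGaseF with DJ101A. The enrichment tables deposited by the authors give a normalized enrichment score and an adjusted p-value per term. The p-values and scores there are the authors' own, and the tool behind them is not given in the sources used here. No column of another series was present (0 columns left unused).

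From the counts, edgeR 4.0.16 in R 4.3.3 gave trimmed-mean (TMM) scaling factors of 1.01 for DJ101A, 0.933 for PNGaseDJ and 1.06 for PNGaseF. Its expression filter kept 18216 genes. The planned quasi-likelihood test needs a spread between replicates, which a single column per group cannot give, so no gene was tested and no p-value was computed. In its place each gene has the difference of log2(CPM + 1) between 2 libraries, and genes at least 2-fold apart on that scale were counted. The pseudocount of 1 CPM understates the difference of low genes. Fold differences of named genes are ratios of scaled CPM without a pseudocount, with an exact 95% binomial counting interval. A gene with 0 reads was compared with a floor of 6 reads (3 read pairs) per library, which is 0.0983 CPM in DJ101A, 0.0936 in PNGaseDJ and 0.0954 in PNGaseF before scaling, and is written as "at least". Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Shares of a library's reads carry a 95% Wilson interval.

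Before the data were examined, 33 gene lists were fixed, among them markers of muscle, neurons, intestine, sperm, oocytes, germ line and embryos. Each list's median log2 difference was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. That percentile describes these libraries and is no test. The list of mitochondrial genome transcripts matched 0 symbols and was replaced by the share of reads on the mitochondrial chromosome. Lists can share genes, and genes with near-identical copies, such as collagens and histones, can trade reads.

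The rule for named genes, as fixed beforehand, relied on adjusted p-values. After the tables were seen it was restated without them. It takes, per comparison, the 6 highest and the 6 lowest log2 differences among genes with a mean of at least 5 CPM. From each list it takes up to 2 members with the largest difference of at least 2-fold, or else the member with the highest mean CPM. It adds png-1, skn-1 and hsp-4. For PNGaseDJ against PNGaseF only the highest and lowest genes are named. The text prints the members that matter most.

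The steps were tested on simulated data with counting error only. For PNGaseDJ against DJ101A, 200 of 17811 genes were changed. The 2-fold threshold was passed by 0 of 50 genes changed by 1.5-fold, 35 of 50 changed by 2.5-fold, 46 of 50 changed by 4-fold and 50 of 50 changed by 8-fold. Of the 17611 unchanged genes 0 passed, and for PNGaseF against DJ101A 0 of 17811 unchanged genes passed. Both enzymes share the DJ101A library, so 3 unchanged libraries were simulated for the correlation of both comparisons, with counting error alone and with an equal spread of 0.477 log2 units (SD) per library, which gives the observed SD of the PNGaseDJ differences.

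Alternatives fixed beforehand and run were DESeq2's size factors, upper-quartile scaling, library totals, no expression filter, a mean of at least 5 CPM, and scaling with only the compared groups. Alternatives added after seeing the data were pseudocounts of 0.1 and 5 CPM, thresholds of 1.5-fold and 4-fold, a mean of at least 20 CPM, leaving out the cuticle and molting lists, and keeping only genes listed for PNGaseF. Those that need replicates were left out. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.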

Results

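Whole wild-type Caenorhabditis elegans were exposed to bacteria making PNGaseDJ, PNGaseF or DJ101A, an inactive PNGase mutant that served as the control. A PNGase is an enzyme that removes N-linked glycans from proteins. Poly(A)-selected RNA of the animals was sequenced, and each of the 3 conditions is represented by 1 column of read counts per gene. The DJ101A library held 61052972 reads in genes, the PNGaseDJ library 64100201 and the PNGaseF library 62868888. At least 1 read was found for 17714 genes in DJ101A and 18422 in PNGaseDJ, and for 15841 of the 17582 genes listed for PNGaseF. The columns carry no replicates, so a difference given here has no replicate check and compares libraries, not conditions. Intervals on fold differences cover counting error only.

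Gene families with large shares of the reads differed between the libraries. Genes named col, which encode cuticle collagens, took 4.62% of the reads in DJ101A (95% Wilson interval 4.61 to 4.62), 7.64% in PNGaseDJ (7.63 to 7.65) and 2.49% in PNGaseF (2.48 to 2.49). Yolk protein genes (vit) took 5.63%, 5.79% and 4.70%, and the mitochondrial chromosome took 1.76%, 2.08% and 2.02%, in the same order. The 10 most abundant genes took 9.29%, 10.03% and 8.72%. Counts of 0 were more frequent in the PNGaseF library. Among genes with at least 100 reads in both other libraries, 315 of 12155 (2.59%) had 0 reads in PNGaseF, against 45 of 11647 in DJ101A and 17 of 11706 in PNGaseDJ. Of the 315 genes, 44 were in the cuticle collagen or molting lists and 271 were outside them.

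The comparison of PNGaseDJ with DJ101A asked which transcripts differ when the enzyme is active. Cuticle collagen transcripts were higher in the PNGaseDJ library, with a median log2 difference of 0.83 over 158 measured genes, of which 66 were at least 2-fold higher and 11 at least 2-fold lower. UDP-glucuronosyltransferases, which attach sugar groups to small fat-soluble molecules, were also higher, with a median of 0.50 over 63 genes (18 higher, 4 lower). Cytosolic ribosomal protein transcripts were lower, with a median of -0.51 over 81 genes and 2 of them at least 2-fold lower. Sperm genes had a median of -0.34 over 85 genes (4 higher, 9 lower), and by families chosen after the values were seen it was -0.41 for 31 msp genes, -0.68 for 12 ssp genes and 0.22 for 29 spe genes. In all, 1150 of 18216 genes were at least 2-fold higher and 1096 at least 2-fold lower (12% together). The majority turned to lower genes with library totals (979 higher, 1300 lower) and upper-quartile scaling (1089 and 1152), a 1.5-fold threshold (2700 and 2881) and without the cuticle and molting lists (1067 and 1077). Over the 17424 genes listed for PNGaseF it also turned (953 and 1096), and that set by its construction leaves out genes with few reads in DJ101A. The split moved the other way with a mean of at least 20 CPM (153 and 76), a 4-fold threshold (160 and 87) and a pseudocount of 5 CPM (286 and 170).

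The 6 highest genes of this comparison included 4 named col. The collagen gene col-63 (WBGene00000639, chromosome I, 8243694 to 8244963) had 0 reads in DJ101A and 12861 in PNGaseDJ, at least 2218-fold more. Y47D7A.15 (V, 4431695 to 4433187) had 0 and 9623 reads, at least 1660-fold more. The gene col-120 (IV, 9260610 to 9261787) was 271-fold higher (182 to 423), from 0.776 to 210.0 CPM, and col-175 (X, 9233638 to 9234618) was 262-fold higher (158 to 468). The gene rol-1 (II, 12172573 to 12176069), named for the rolling movement of its mutants, was 374-fold higher (218 to 702). The gene col-49 (I, 3137185 to 3138447) had 0 and 4858 reads, at least 838-fold more. Because collagen genes resemble each other, reads of single members can be traded among them and the values of single members are uncertain.

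The lowest gene was scl-19 (WBGene00013971, V, 18731991 to 18732772), which encodes a secreted protein of the SCP family, with 1572 reads in DJ101A and 0 in PNGaseDJ, at least 253-fold lower. Its neighbour asp-18 (V, 18730174 to 18731679), a predicted aspartyl protease, had 977 and 0 reads, at least 157-fold lower. Both genes also had 0 reads in PNGaseF. Y41C4A.32 (III, 11721706 to 11723607) was 18.8-fold lower (17.7 to 19.9), from 799.9 to 42.6 CPM. F55C9.5 (V, 19290574 to 19293125) was 18.6-fold lower (13.2 to 26.5), ZK675.4 (II, 7911315 to 7912119) 23.3-fold lower (14.9 to 36.6) and F55C9.3 (V, 19287009 to 19288173) 11.9-fold lower (9.64 to 14.9). Y41C4A.32, F55C9.5 and ZK675.4 overlap another annotated gene. Counting without strand leaves the values of overlapping genes uncertain.

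Lists are described by their median and by its percentile among 10000 expression-matched random lists, as a description of these libraries. In PNGaseDJ against DJ101A the cuticle collagens and the UDP-glucuronosyltransferases lay at percentile 100 and the ribosomal and sperm lists at percentile 0. The random lists were not matched on gene length, and a part of gene length in these medians was not tested. With genes at 0 reads set to the floor, the collagen median was 0.78. Among the glucuronosyltransferases, ugt-26 was 5.79-fold higher (5.27 to 6.36) and ugt-31 was 5.20-fold higher (4.70 to 5.74). The 68 cytochrome P450 genes had a median of 0.16 at percentile 98.7 (12 higher, 7 lower), and cyp-13A2 was 7.85-fold higher (5.53 to 11.4). Fasting and beta-oxidation genes had a median of 0.36 over 48 genes at percentile 100, with 4 at least 2-fold higher and 4 lower. The acyl-CoA dehydrogenase gene acdh-2, which overlaps another gene, was 4.42-fold higher (3.68 to 5.34) and its relative acdh-5 was 4.31-fold lower (3.55 to 5.33). Fatty acid synthesis and desaturation genes had a median of -0.25 over 23 genes at percentile 0.05, with 0 higher and 3 lower. The fatty acid elongases elo-2 and elo-6 were 2.39-fold (2.2 to 2.61) and 2.22-fold (2.08 to 2.37) lower.

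Of the ribosomal protein genes, rpl-36 (III, 7180251 to 7180647) was 2.05-fold lower (1.92 to 2.19), from 91.3 to 44.5 CPM, and rpl-37, which overlaps another gene, was 3.96-fold lower (2.55 to 6.31). In defence-related lists members went both ways. The 39 lysozymes and saposin-like proteins had a median of -0.21 at percentile 0.60 (5 higher, 3 lower). Their member ilys-2, an invertebrate-type lysozyme, was 7.19-fold higher (6.12 to 8.42), and spp-12 was 19.2-fold lower (11.5 to 34.7). The 160 C-type lectins had a median of 0.01 at percentile 73.0 (16 higher, 11 lower), with clec-53 at 6.75-fold higher (5.41 to 8.52) and clec-198 at 268 and 0 reads, at least 43.2-fold lower. The 27 immune effectors had a median of -0.09 at percentile 12.5 (4 higher, 3 lower). The flavin-containing monooxygenase gene fmo-2 was 9.37-fold higher (7.33 to 12.1) and the thaumatin-like gene thn-1 was 5.73-fold lower (4.59 to 7.14). The 40 genes of the intracellular pathogen response, a programme induced by microsporidia and viruses, had a median of -0.12 at percentile 25.8 (2 higher, 7 lower), and pals-5 was 17.3-fold lower (7.74 to 48.4). The 36 epidermal antimicrobial peptide genes had a median of -0.10 at percentile 20.3 (5 higher, 2 lower).

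Lists tied to N-glycans and protein folding were near 0 in this comparison. The 42 genes of N-glycan synthesis and processing had a median of 0.05 at percentile 58.2 (2 higher, 0 lower), the 33 proteasome subunits 0.01 at percentile 11.2 and the 9 genes of the mitochondrial unfolded protein response 0.07 at percentile 55.5, and the sign of each of these medians turned with library totals as the scaling. The 2 higher N-glycan genes were uggt-2, at 8.32-fold (5.56 to 12.9), and algn-14, at 9.51-fold (4.61 to 23), and both overlap another gene. The 24 genes of the endoplasmic reticulum (ER) unfolded protein response had a median of -0.08 at percentile 3.35, and the 17 cytosolic heat shock genes -0.10 at percentile 8.69. The worm's own cytosolic PNGase gene, png-1, stood at 31.5 CPM in DJ101A and 32.5 CPM in PNGaseDJ, a ratio of 1.03 (0.944 to 1.13). The ER chaperone gene hsp-4 stood at 423 and 436 CPM, and skn-1, a stress-response transcription factor whose activity depends on png-1, at 156 and 177 CPM. Both png-1 and skn-1 overlap another gene.

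The other lists in PNGaseDJ against DJ101A had medians from -0.32 to 0.28. The 45 glutathione S-transferase and phase II genes had a median of 0.04 at percentile 72.6, with the overlapping gene gst-4 2.73-fold higher (2.39 to 3.12), the 150 molting and pharyngeal cuticle genes 0.00 at percentile 56.7 (17 higher, 8 lower) and the 20 basement membrane genes 0.01 at percentile 37.1, and the sign of these 3 medians depended on the scaling. The mixed list of 17 DAF-16 and oxidative stress targets had a median of 0.14 at percentile 82.7. The 14 propionate and methionine cycle genes had 0.17 at percentile 85.7 and the 6 vitellogenins 0.28 at percentile 92.9, with vit-1 2.24-fold higher (2.21 to 2.26). The 75 lysosome and autophagy genes had a median of -0.06 at percentile 0.630 and the 38 nuclear genes of the mitochondrial respiratory chain -0.04 at percentile 7.54. Among cell type and stage markers, 48 neuron genes had a median of -0.32 at percentile 0.290, 22 muscle genes 0.18 at percentile 91.4 and 14 intestine genes 0.24 at percentile 95.3. The 21 oocyte genes had a median of -0.08 at percentile 0.895, the 19 germ line genes 0.12 at percentile 71.5, the 41 zygotic embryo genes 0.00 at percentile 60.3 and the 48 histone genes -0.01 at percentile 42.1.

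PNGaseF was compared with DJ101A to ask which transcripts differ with the other active enzyme. DJ101A is a single mutant and cannot be the inactive form of both enzymes. For an enzyme that DJ101A does not derive from, activity and the identity of the protein cannot be told apart. Cuticle collagen transcripts were lower in the PNGaseF library, with a median log2 difference of -2.0 over 143 measured genes, of which 98 were at least 2-fold lower and 8 at least 2-fold higher. Muscle transcripts were also lower, with a median of -1.29 over 22 markers, 17 of them at least 2-fold lower and 0 higher. Molting and pharyngeal cuticle genes had a median of -0.64 over 142 genes (5 higher, 65 lower), and basement membrane and extracellular glycoprotein genes -0.71 over 20 genes (0 higher, 7 lower). Several C-type lectin and pathogen response genes were higher. Of 17424 genes, 1772 were at least 2-fold higher and 2685 at least 2-fold lower (25.6% together). Of the measured collagens 34 had 0 reads in PNGaseF, the library in which such counts were most frequent.

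**Figure D1:**
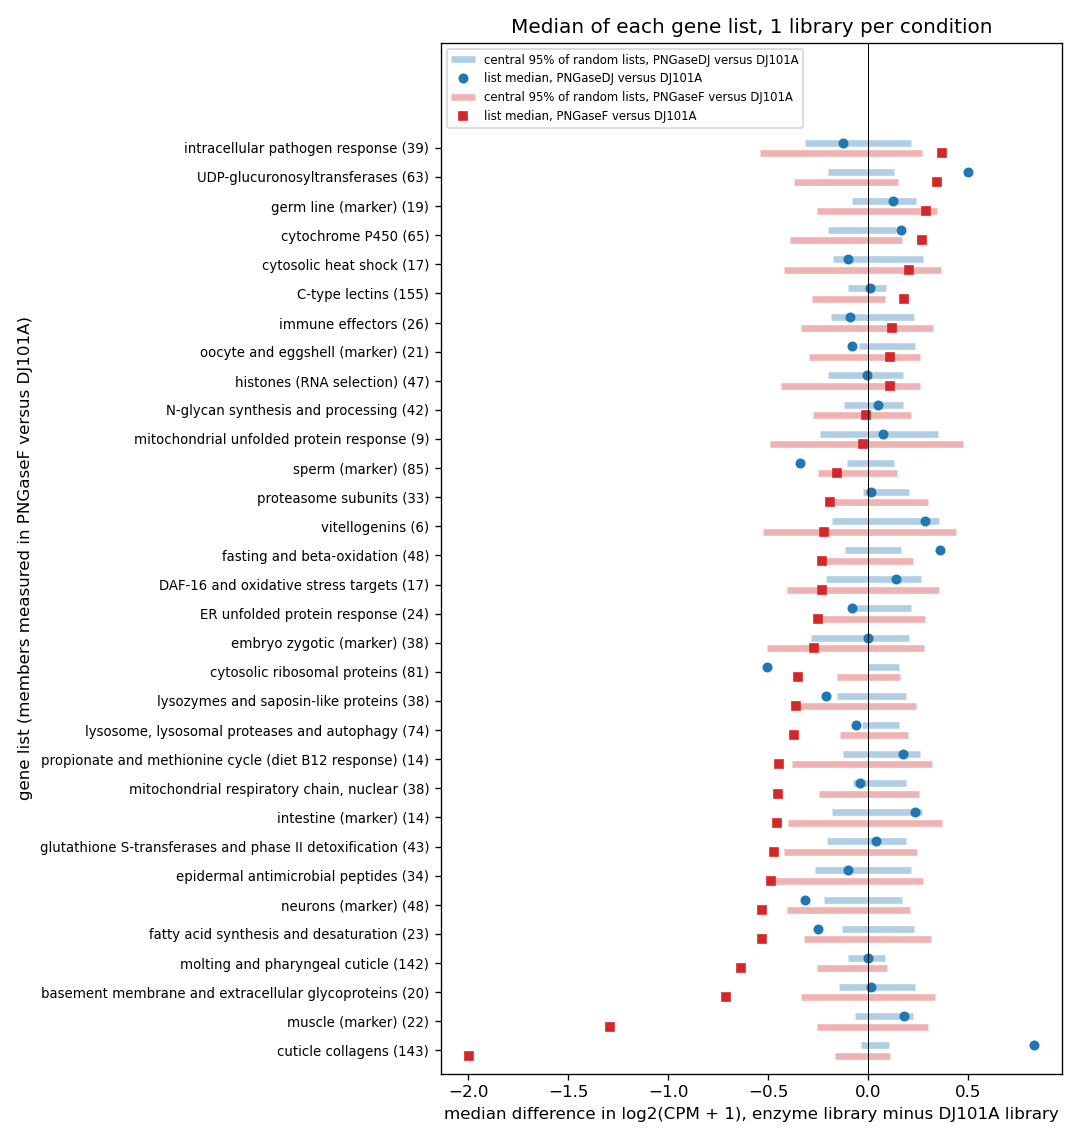
Median log2(CPM + 1) difference of each gene list (horizontal axis) for PNGaseDJ and PNGaseF against DJ101A (points), with bars for the central 95% of 10000 expression-matched random lists. The cuticle collagens stand at 0.83 for PNGaseDJ and -2.0 for PNGaseF, and the muscle markers at 0.18 and -1.29.

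Of the 6 lowest genes in PNGaseF, 5 were collagens, and 3 of these had 0 reads. The gene col-41 (WBGene00000618, X, 15175032 to 15176481) had 6606 reads in DJ101A and 0 in PNGaseF, at least 1184-fold lower, and col-14 (IV, 7753408 to 7754656) had 5494 and 0 reads, at least 984-fold lower. The gene col-77 (II, 8358228 to 8359381) had 4573 and 0 reads, at least 819-fold lower. The genes col-125 (IV, 11225506 to 11226516) and col-147 (V, 9632029 to 9633338) were 110.3-fold (93.5 to 131) and 119.5-fold (96.7 to 150) lower, from 471 to 4.27 CPM and from 309 to 2.59 CPM. R12E2.7 (I, 4153966 to 4154424) had 3811 and 0 reads, at least 683-fold lower. Of these genes, col-41, col-14, col-125 and col-147 overlap another gene. The molting list held abu-8 and abu-12, with 1275 and 1149 reads in DJ101A and 0 in PNGaseF, at least 228-fold and 206-fold lower.

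The highest gene was B0222.10 (WBGene00015058, V, 9158416 to 9159540), annotated as a non-coding RNA, with 0 reads in DJ101A, 91 in PNGaseDJ and 9102 in PNGaseF, at least 1411-fold higher in PNGaseF than in DJ101A. F35C5.3 (II, 12888771 to 12890553) had 0 reads in both other libraries and 3284 in PNGaseF, at least 509-fold higher. The carboxylesterase gene cest-12 (III, 12101745 to 12107541) was 192-fold higher (97.2 to 445), from 0.259 to 49.6 CPM, and also stood at 22.5 CPM in PNGaseDJ. The predicted trypsin-like protease gene try-13 (V, 7440107 to 7441522) had 0 and 2494 reads, at least 387-fold higher, and scl-15 (II, 3283660 to 3284658) had 0 and 2330 reads, at least 361-fold higher. F59B2.12 (III, 9017601 to 9020965) had 0 and 2404 reads, at least 373-fold higher. Both scl-15 and F59B2.12 overlap another gene.

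Muscle markers lay at percentile 0. The myosin heavy chain genes myo-1 (I, 7258946 to 7267057) and myo-2 (X, 12468061 to 12475348), which are expressed in the pharynx, were 15-fold (14 to 16.0) and 9.54-fold (9.04 to 10.1) lower. Their levels went from 402 to 26.9 CPM and from 429 to 45.0 CPM. The basement membrane list, also at percentile 0, held the perlecan gene unc-52 (II, 14647321 to 14684456), 2.91-fold lower (2.79 to 3.04), and the ADAMTS protease gene gon-1 (IV, 9934206 to 9953433), 6.04-fold lower (4.75 to 7.67). Neuron markers had a median of -0.53 over 48 genes at percentile 0.390 (0 higher, 13 lower). Among them rab-3, a synaptic vesicle GTPase gene, was 10.2-fold lower (8.28 to 13), and unc-17, the vesicular acetylcholine transporter gene, had 372 and 0 reads, at least 66.7-fold lower. Intestine markers had a median of -0.46 over 14 genes at percentile 1.26 (0 higher, 3 lower), with the proton pump subunit gene vha-6 at 2.59-fold lower (2.46 to 2.72) and the peptide transporter gene pept-1 at 2.39-fold lower (2.24 to 2.56). Markers of oocytes (median 0.11 over 21 genes, percentile 83.0) and germ line (0.29 over 19 genes, percentile 94.4) were not lower. Except for myo-2, vha-6 and pept-1, the genes named here overlap another gene.

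**Figure D2:**
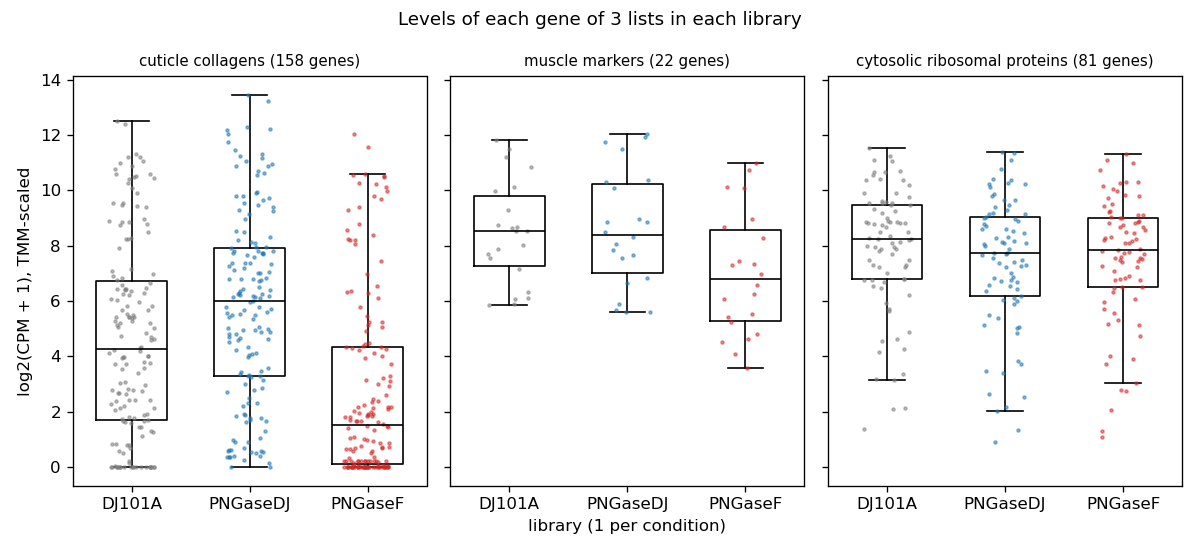
Level of each gene, as log2(CPM + 1) on the vertical axis, in the 3 libraries for 158 cuticle collagens, 22 muscle markers and 81 ribosomal protein genes. Points are genes, boxes show the quartiles and median, and whiskers reach 1.5 times the box height. Median levels were 18.3, 62.9 and 1.87 CPM for the collagens, 369, 337 and 110.1 CPM for muscle and 305, 213 and 227 CPM for ribosomal proteins in DJ101A, PNGaseDJ and PNGaseF.

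Detoxification and defence genes were split in PNGaseF. UDP-glucuronosyltransferases had a median of 0.35 over 63 genes at percentile 99.99 (16 higher, 7 lower) and cytochrome P450 genes 0.27 over 65 genes at percentile 99.6 (14 higher, 5 lower). The gene cyp-33C6 was 23.6-fold higher (12.2 to 52.2), ugt-32 had 0 and 463 reads, at least 71.8-fold higher, and ugt-36 had 460 and 0 reads, at least 82.4-fold lower. C-type lectins had a median of 0.18 over 155 genes at percentile 99.9 (40 higher, 28 lower), with clec-95 and clec-134 at 0 reads in DJ101A and 2069 and 1646 reads in PNGaseF, at least 321-fold and 255-fold higher. The intracellular pathogen response had a median of 0.37 over 39 genes at percentile 99.3 (11 higher, 3 lower). Its neighbouring members pals-39 (V, 12441663 to 12443854) and pals-38 (V, 12445164 to 12446995) were 19.4-fold (14.6 to 25.8) and 12.9-fold (9.95 to 17) higher. Immune effectors had a median of 0.12 over 26 genes at percentile 74.4 (7 higher, 2 lower), and irg-2 was 5.41-fold higher (4.62 to 6.33). Lysozymes and saposin-like proteins had a median of -0.36 over 38 genes at percentile 2.26 (4 higher, 7 lower), among which ilys-2 was 10.1-fold higher (8.62 to 11.8) and spp-7 10.4-fold lower (7.27 to 15.4). Glutathione S-transferase and phase II genes had a median of -0.47 over 43 genes at percentile 0.835 (2 higher, 8 lower), although gst-4, which overlaps another gene, was 3.55-fold higher (3.12 to 4.04). Epidermal antimicrobial peptides had a median of -0.49 over 34 genes at percentile 3.39.

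Metabolic and housekeeping lists were mostly lower in PNGaseF. Fatty acid synthesis and desaturation genes had a median of -0.53 over 23 genes at percentile 0.110 (0 higher, 7 lower), with elo-2 at 5.07-fold lower (4.54 to 5.67) and the desaturase gene fat-7 at 3.89-fold lower (3.31 to 4.58). Fasting and beta-oxidation genes had a median of -0.23 over 48 genes at percentile 3.05, with the acyl-CoA oxidase gene acox-1.3 at 23.9-fold lower (11.9 to 56.3). Propionate and methionine cycle genes had a median of -0.44 over 14 genes at percentile 1.16, and the S-adenosylmethionine synthetase gene sams-1 was 2.05-fold lower (1.99 to 2.11). Ribosomal proteins had a median of -0.35 over 81 genes at percentile 0, with 0 members at least 2-fold apart, the respiratory chain -0.45 over 38 genes at percentile 0.020 and the lysosome and autophagy genes -0.37 over 74 genes at percentile 0. The random lists were not matched on gene length. In PNGaseF the shortest of 20 length bins had a median of -0.18 and the longest 0.03, among genes with at least 5 CPM outside the muscle markers. Counted from the shortest, the lowest median was -0.21 in bin 3 and the highest 0.17 in bin 17. A part of gene length in the list medians was not tested. Proteasome subunits had a median of -0.19 at percentile 1.61, and the 6 vitellogenins -0.22 at percentile 21.4. DAF-16 and oxidative stress targets had a median of -0.23 over 17 genes at percentile 13.9 and sperm genes -0.16 over 85 at percentile 15.8. Zygotic embryo genes had -0.27 over 38 at percentile 25.8 and histones 0.11 over 47 at percentile 86.3.

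The ER unfolded protein response had a median of -0.25 over 24 genes at percentile 2.86 in PNGaseF, although the ER chaperone gene enpl-1, which overlaps another gene, was 1.54-fold higher (1.52 to 1.56). N-glycan genes had a median of -0.01 over 42 genes at percentile 53.9 (3 higher, 1 lower), and the mitochondrial unfolded protein response -0.03 over 9 genes at percentile 41.3, both with a sign that depended on the scaling. Among N-glycan genes, algn-14, which overlaps another gene, was 12.9-fold higher (6.33 to 30.6), and the core fucosyltransferase gene fut-8 (V, 5986990 to 5990483) was 5.23-fold lower (3.83 to 7.31). The 17 cytosolic heat shock genes had a median of 0.20 at percentile 86.1, and hsp-70, which overlaps another gene, was 2.86-fold higher (2.77 to 2.96). The gene png-1 stood at 20.7 CPM in PNGaseF, 1.52-fold lower (1.38 to 1.68) than in DJ101A, hsp-4 at 411 CPM and skn-1 at 202 CPM.

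PNGaseDJ and PNGaseF were compared directly, which leaves out the control. Cuticle collagens were higher in PNGaseDJ, with a median of 2.84 over 158 genes (118 higher, 5 lower), or 2.78 with genes at 0 reads set to the floor. Over the 143 collagens listed for PNGaseF the median was 2.91 (112 higher, 5 lower). Muscle markers had a median of 1.41 (21 of 22 higher), basement membrane genes 0.77 (9 of 20 higher), molting genes 0.71 over 150 genes (67 higher, 7 lower) and intestine markers 0.66 over 14 genes (3 higher). The intracellular pathogen response was lower in PNGaseDJ, with a median of -0.52 over 40 genes (1 higher, 16 lower) at percentile 0.040. Cytosolic heat shock genes had a median of -0.34 over 17 genes (0 higher, 3 lower) at percentile 1.56, which was 2.88 with upper-quartile scaling and 4.33 with library totals. Immune effectors had a median of -0.27 over 27 genes (3 higher, 11 lower) at percentile 3.48, inside the central 95% of random lists. Of 18216 genes, 2470 were at least 2-fold higher in PNGaseDJ and 1510 at least 2-fold lower (21.8% together). Library totals as the only scaling moved the median of all genes from 0.02 to -0.09 and gave 2054 higher and 1891 lower.

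The 6 genes highest in PNGaseDJ relative to PNGaseF were collagens. The gene col-125 was 387-fold higher (328 to 460), at 1653 against 4.27 CPM. The genes col-14, col-146, col-77, col-162 and col-161 had 0 reads in PNGaseF and 16767, 14914, 14493, 13499 and 12598 reads in PNGaseDJ, at least 3109-fold, 2765-fold, 2687-fold, 2503-fold and 2336-fold more. The lowest were B0222.10 (89.9-fold lower, 66.6 to 122), F35C5.3 (at least 492-fold lower), scl-15 (at least 349-fold), try-13 (224-fold, 95.8 to 692), clec-95 (at least 310-fold) and srlf-18 (at least 298-fold).

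Differences of both enzymes from DJ101A were correlated across 17424 genes, with Pearson's r of 0.373 and a covariance of 0.257. Genes are not independent replicates, and both comparisons use the same DJ101A library. Counting error alone in 3 simulated unchanged libraries gave r of 0.516 and a covariance of 0.00761, and an equal spread of 0.477 log2 units in each gave 0.508 and 0.232. Higher in both libraries were 406 genes, where independent lists of 953 and 1772 genes would share 96.9, and lower in both were 597, where lists of 1096 and 2685 would share 169. Higher in PNGaseDJ and lower in PNGaseF were 117 genes (147 for independent lists), and the opposite held for 20 (111 for independent lists). The simulation with equal spread gave 319 genes higher in both and 370 lower in both with no effect. Its spread was set from the PNGaseDJ differences alone. The PNGaseF differences were wider, with an SD of 1.02 against 0.696 over 18216 genes for PNGaseDJ. The simulated r, covariance and shared genes are therefore not like for like with the observed ones. How much of the excess over independent lists comes from the shared control cannot be told, since that control is a single library and cannot be split.

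The authors' deposited table for PNGaseDJ held log2 values that correlated with those used here at r = 0.999 over 18216 genes, and the sign was the same for 92.4% of the 17733 genes with a value other than 0. In the authors' deposited table for PNGaseF r was 1.00 over 17424 genes and the sign was the same for 97.4%. By the authors' deposited tables, 979 genes were at least 2-fold higher and 1300 lower in PNGaseDJ, and 1945 higher and 2566 lower in PNGaseF. The deposited values come from the same counts and differ from those used here in scaling only. The close agreement was therefore set by construction, and the 979 and 1300 genes repeat the numbers found with library totals.

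Enrichment results were taken from the authors' tables as given. The deposited log2 values compare 1 count column with 1. The adjusted p-values below are therefore not read here as a measure of variation between animals or libraries. For PNGaseDJ the authors' deposited table listed 11 Reactome pathways, each with a negative normalized enrichment score, from -1.74 to -1.43. In the authors' deposited table the joining of the 60S ribosomal subunit had a score of -1.74 (adjusted p = 0.00305), and translation, with 175 genes, -1.59 (adjusted p = 0.00566). For PNGaseF the authors' deposited table listed 217 gene ontology terms, 73 with a positive and 144 with a negative score. The positive terms of the authors' deposited table included DNA repair at 2.43 (adjusted p = 3.4e-08), double-strand break repair at 2.33 (adjusted p = 2.8e-06), the meiotic cell cycle at 1.91 (adjusted p = 2.8e-06) and the defence response at 1.5 (adjusted p = 0.000344). Its negative terms, again in the authors' deposited table, included cuticle development at -2.27 (adjusted p = 1.3e-05), sarcomere organization at -2.27 (adjusted p = 2.6e-05), muscle contraction at -2.19 (adjusted p = 6.5e-06) and chemical synaptic transmission at -1.87 (adjusted p = 6.1e-06).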

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

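The tests of library scaling, of reads traded among collagen genes and of the molting cycle were chosen only after the collagen medians had been seen.

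Cuticle collagens drew attention because they stood on opposite sides of DJ101A, with a median log2 difference of 0.83 in PNGaseDJ over 158 genes (0.78 over the 143 measured in both comparisons) and -2.0 in PNGaseF over those 143, and with 1 library per condition this difference was not tested. Over 4 scalings the medians nearest to 0 were 0.71 in PNGaseDJ and -1.94 in PNGaseF, so neither part hinges on the choice among these 4. The scalings lie close together, and library totals moved named genes by at most 0.17 log2 units. They could not have brought either median to 0, so this check does not decide on library scaling as a cause. Reads traded among near-identical collagens would leave their sum in place, whereas the summed level was 84711 CPM in PNGaseDJ and 24426 CPM in PNGaseF against 49377 CPM in DJ101A, log2 ratios of 0.78 and -1.02. A candidate explanation of the PNGaseF part is that its animals were at another point of the molting cycle or of adult life. The molting and pharyngeal cuticle list had a median of -0.64, at percentile 0 of the random lists. That list mixes families, which were split only after the values were seen. In PNGaseF the medians were -3.81 for abu, -1.50 for grd, -1.35 for ptr, -1.08 for wrt and -0.69 for grl genes. The pqn genes, 50 of its 150 members measured in PNGaseDJ, had -0.14. Muscle markers (-1.29) and basement membrane genes (-0.71) also lay at percentile 0 there, and UDP-glucuronosyltransferases (0.35) at percentile 99.99. A lower molting list is therefore not particular to that explanation. For the PNGaseDJ part that list lay at percentile 56.7 with members on both sides, which leaves the explanation open. There abu genes had a median of 0.78 (5 higher, 0 lower) and grd genes 0.32 (3 higher, 2 lower). The medians were -0.03 for pqn (5 higher, 1 lower), -0.03 for ptr (2 higher, 3 lower), 0.00 for grl and -0.01 for wrt genes. An effect of either enzyme stays open as untested.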

How the results depend on the processing

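The pseudocounts, the 1.5-fold and 4-fold thresholds, the mean of at least 20 CPM, the runs without the cuticle and molting lists or with only genes listed for PNGaseF, and the scalings of the overlap (all), of the lists (upper quartile and totals) and of single genes (totals) were chosen after seeing the data. No paired analysis was possible because each group has a single count column that carries no replicate number. For the same reason the DESeq2 Wald test, limma-voom, robust dispersions, an adjusted p under 0.01, a 1.5-fold glmTreat threshold, leaving out each library, camera with an estimated correlation and fry were not run.

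DESeq2's size factors, upper-quartile scaling, library totals, no expression filter and scaling with only the compared groups left each count of genes at least 2-fold apart within 1.5 times of its main value, as did leaving out the cuticle and molting lists (2144 genes for PNGaseDJ against DJ101A, 4281 for PNGaseF against DJ101A and 3783 for PNGaseDJ against PNGaseF). Keeping only genes listed for PNGaseF gave 2049 genes for PNGaseDJ against DJ101A and 3839 for PNGaseDJ against PNGaseF. The other settings are given in the same order of comparisons. A mean of at least 5 CPM gave 786, 1910 and 1722 genes, and a mean of at least 20 CPM gave 229, 715 and 639. Fewer genes enter under these filters by construction, and the share at least 2-fold apart was also smaller, at 7.62%, 18.5% and 16.7% with 5 CPM and 3.62%, 11.3% and 10.1% with 20 CPM. A pseudocount of 0.1 CPM gave 5049, 6984 and 6665 genes and 5 CPM gave 456, 1463 and 1280, since a larger pseudocount shrinks the differences of low genes. By construction a 1.5-fold threshold gave more genes (5581, 8223 and 7581) and a 4-fold threshold fewer (247, 1055 and 878). Under the 5 CPM filter the overlap held 155 genes higher in both and 180 lower in both. For PNGaseDJ against DJ101A the majority turned from higher (1150 and 1096 lower) to lower with upper-quartile scaling (1089 and 1152), library totals (979 and 1300), the 1.5-fold threshold (2700 and 2881), without the cuticle and molting lists (1067 and 1077) and with only genes listed for PNGaseF (953 and 1096), where by construction genes with few reads in DJ101A are left out. It moved towards higher genes with a mean of at least 20 CPM (153 and 76), the 4-fold threshold (160 and 87) and a pseudocount of 5 CPM (286 and 170).

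List medians kept their place outside or inside the central 95% of random lists for 96 of 96 values with DESeq2's size factors, and for 95 of 96 with upper-quartile scaling and with library totals. The exception was cytosolic heat shock in PNGaseDJ against PNGaseF, at -0.38 (percentile 2.88) and -0.43 (percentile 4.33), for which the cause was not tested. The sign turned for 3, 11 and 15 medians in the same order, 0 of them outside the central 95%, and each had a main value within 0.104 of 0. Of 144 differences of named genes, 44 involve a library with 0 or 1 read and have no closed counting interval. Of the other 100, 13 moved beyond their interval with DESeq2's size factors and 27 with library totals, by at most 0.03 and 0.17 on the log2 scale over all 144, and 0 of those past 2-fold turned their sign. Depth limits differences from 0 reads to bounds at the floor. Counting error alone put 0 of 17611 and 0 of 17811 simulated unchanged genes past 2-fold for PNGaseDJ and PNGaseF against DJ101A.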

Other observations

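The families, shared genes and neighbouring genes described here, and the tests of germ-line RNA and of few RNA molecules, were chosen only after the values were seen, as were the way the run of neighbouring genes was judged and the share of genes in such runs.

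Some gene families are described here by their medians, which kept their sign under 4 scalings in both libraries and were not set against random lists. Integrator complex subunits (ints), which process small nuclear RNAs, had a median log2 difference of 0.77 in PNGaseF over 11 genes (3 at least 2-fold higher, 0 lower) and of 0.39 in PNGaseDJ (0 past 2-fold). Neuropeptide receptor genes (npr) had a median of -1.0 in PNGaseF (4 higher, 19 lower) and -0.43 in PNGaseDJ (4 higher, 8 lower). The subunits of the vacuolar proton pump (vha), which are also in the lysosome list, had a median of -0.73 in PNGaseF over 20 genes (0 higher, 4 lower). Cuticulin-like genes (cutl), which encode other cuticle proteins, were lower in both libraries, at -1.25 in PNGaseF (15 lower, 0 higher) and -0.83 in PNGaseDJ (9 lower, 2 higher), whereas collagens differed in direction. The astacin metalloproteases (nas), 4 of which are also in the molting list, had a median of 0.64 in PNGaseDJ over 32 genes (11 higher, 1 lower) and -0.29 in PNGaseF over 27 genes (6 higher, 10 lower).

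Of genes with a mean of at least 20 CPM, 41 were at least 2-fold higher in both enzyme libraries than in DJ101A and 48 at least 2-fold lower. The higher genes included the X chromosome dosage gene sdc-3 (20.2 CPM in DJ101A, 53.0 in PNGaseDJ and 89.8 in PNGaseF), the mismatch repair gene pms-2 (45.2, 116 and 180 CPM) and the collagens col-63 (0, 215 and 2.83 CPM), col-120 (0.776, 210.0 and 4.50 CPM) and col-60 (0, 71.2 and 1.68 CPM). The lower genes included the collagens dpy-14 (951, 321 and 292 CPM), dpy-17 (505, 200.1 and 172 CPM) and col-74 (678, 76.4 and 21.1 CPM), the hatching protease gene hch-1 (119.5, 37.1 and 17.4 CPM) and mtre-1 (132, 13.5 and 23.2 CPM). At the scl-19 locus on chromosome V, asp-18 and scl-19 had 0 reads in both enzyme libraries, the adjoining scl-20 (18732798 to 18734481) stood at 116, 13.2 and 18.0 CPM, and the next gene, ZK384.7, had 247, 174 and 209 reads in DJ101A, PNGaseDJ and PNGaseF. Each of these shared differences rests on the single DJ101A library.

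Muscle markers had the lowest median of the marker lists in PNGaseF, at -1.29 over 22 genes. A larger share of germ-line RNA was taken to lower all somatic markers alike, which was not tested. The muscle median lay below the intestine median by a difference of -0.83 (95% interval -1.30 to -0.44, from a bootstrap over the marker genes). Muscle was picked as the lowest list, so a difference below 0 was set by that choice and its interval is no test. Only if all somatic markers fall alike does a gap of this size argue against such a share as the whole cause, for these 2 libraries. Broken RNA would follow gene length, and the muscle median was -1.25 (-1.48 to -1.04, again over genes) after the length trend was removed. Both intervals describe the spread over genes, not over animals or libraries. A lower share of muscle RNA, a lower expression of muscle genes under the enzyme and a difference between the animals that the labels do not record stay open and were not tested.

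In PNGaseF 315 genes had 0 reads with at least 100 in both other libraries. The counting command for PNGaseF is not given, and its share of even counts was 66.5%, against 73.0% in DJ101A and 71.5% in PNGaseDJ. Whether PNGaseF was counted like the other libraries is not known, and a part of this in the 0 counts was not tested. Few RNA molecules in the library would put more genes at 0 reads than at 1 to 20, which held for those with under 200 reads in the lower of the other libraries (163 and 86), but also from there to under 400 (91 and 45) and at 400 or more (61 and 20), so that this comparison decides nothing and leaves the explanation open for the genes under 200. Outside the cuticle and molting lists, the share at 0 reads among those genes predicted 27.9 (at most 39) from there to under 400 and 1.38 (at most 4) at 400 or more, where 79 and 39 genes were at 0 reads. The prediction takes these genes as equally expressed in all libraries, which was not tested for them. Over all measured genes, 2685 of 17424 were at least 2-fold lower in PNGaseF, so equal expression is doubtful. The values therefore argue only against few molecules with equal expression as the whole cause in both ranges. Few molecules together with lower expression of some genes stay open. A deletion that spans neighbouring genes would cover runs of 3 or more, and these held 5 of the 315 genes (1.59%), which argues against it for the set. They formed 1 run on chromosome V, from pqn-63 (start 9616031) to col-146 (end 9631012). The 5 are neighbours only among genes with at least 100 reads in both other libraries, and random sets of such genes reached 4. Inside the run idpc-5, and beside it dop-2, with fewer than 100 reads in 1 of the other libraries, were also at 0. T06E4.7, which lies inside and had 33 reads in DJ101A and 59 in PNGaseDJ, had 236 in PNGaseF and breaks the run. A shorter deletion there cannot be told apart from low expression.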
